A study of Mus musculus with 12 samples.

How the data were processed

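Striatum was dissected from frozen mouse brains, and the submitters' notes name STAR, featureCounts, limma and edgeR and the mm10 build, without versions. The deposited values are named RPKM, but they were log2 CPM. All 12 libraries shared a lowest value of -3.46, the antilogs summed to 920461 to 1070700 per library, and whole reads were recovered from 100% of values within a tolerance of 0.1 read, after subtraction of a prior of 2 reads on average (1.65 to 2.41). The recovered reads came to 18902120 to 24293208 per library, with scaling factors of 0.935 to 1.09, and 1 to 55 genes per library had 0 reads. The 10 most abundant genes took 4.69% to 7.94% of the reads. Before the data were examined the plan was to add 0.1 to RPKM and take logs; as the values were already logs with a prior, they were used as deposited.

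The 15397 genes carried NCBI gene IDs, and 15078 of them matched RefSeq genes on GRCm38, which gave positions. Transcript length and GC content from GENCODE M21 were known for 14305 genes (92.9%). The planned filter, 0.5 in at least 3 libraries, removed no gene.

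Groups were compared with limma (version 3.58.1, R 4.3.3) in 1 fit of group means over all 12 libraries, with an intensity trend and a two-sided moderated test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 15397 genes. The interaction is the drug's change in R6/2 minus its change in wild type. Called lists come from camera with a preset correlation of 0.01 over 36 gene lists (688 of 779 genes measured), adjusted within a comparison. Beside it stand camera with an estimated correlation, under which 1 of all list calls held (homeostatic microglia for the drug in R6/2), and fry. The lists, these tests, the genes to name, leaving out each library, other pseudocounts and filters, a rescaling by median of ratios, a replicate block and separate fits of 6 libraries were chosen before the data were examined. Removal of a GC and length trend, limma-voom on recovered reads, a cortical covariate, and leaving out R6/2 PLX3397 libraries 1 and 2 or both libraries high in choroid plexus genes were chosen after seeing the data. Where libraries were left out of a group of 3, even where 1 remained, the spread was pooled over all groups. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

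Named genes are, for each pair of groups, the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups (predicted genes and pseudogenes left out), up to 4 members with the smallest p of each called list and up to 2 of a list not called. To these come the 10 smallest p of the interaction, the 10 largest products among genes moved back, and 21 genes fixed in advance such as Csf1r, Penk and Acan. The text names a part of the genes this rule gives, and a withheld gene among them is not reported here. Members listed beside a list's count beyond this rule were picked after their values were seen.

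In 5 simulations of R6/2 against wild type on vehicle, with 200 genes changed among 15397, the test recovered 9.6% of 1.5-fold changes, 41.2% of 2-fold, 81.6% of 4-fold and 91.6% of 8-fold changes, with 6.2 false calls per simulation. The simulated noise was independent between genes, so these rates leave out shifts that many genes of a library share. Replicates correlated at r = 0.938 to 0.986, and their chi-square per degree of freedom of 15.5 to 149 shows a spread far above counting error.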

Results

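RNA was sequenced from the striatum of 12 C57BL/6 mice to ask what removal of microglia does to gene expression in R6/2 mice, which carry a fragment of mutant huntingtin and are a model of Huntington's disease. The study's focus was on striatal volume, the extracellular matrix and perineuronal nets, the coats of matrix around some neurons. R6/2 and wild-type mice were given vehicle or chow with PLX3397, an inhibitor of the microglial survival receptor Csf1r, which gave 4 groups with n = 3 mice in each. The chow held 275 ppm of the drug, and treatment ran from week 7 to week 11 in all groups. Values were deposited as log2 CPM (read counts scaled to library size) for 15397 genes, and each library held 18902120 to 24293208 reads assigned to genes. Changes below are log2 differences ± SE between groups with n = 3 each, from limma with Benjamini-Hochberg adjustment.

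The relation to transcript GC content and the levels of genes from neighbouring regions differed between libraries. Across genes, which are not independent replicates, the PLX3397 change rose with transcript GC in wild type (Spearman's rho 0.510) and fell with it in R6/2 (rho -0.471). Slc17a7, a vesicular glutamate transporter of cortical neurons, was at 2.79 and 3.06 log2 CPM in R6/2 PLX3397 libraries 1 and 2, at 5.67 in wild-type PLX3397 library 1 and at 7.30 to 9.86 in the others. Ttr, the transthyretin of choroid plexus, was picked after its values were seen: it was at 12.1 log2 CPM in R6/2 vehicle library 1, at 9.89 in wild-type PLX3397 library 1 and at 4.01 to 6.09 elsewhere. Each count is followed by the count after a GC and length trend was removed from every library, which covered 14305 genes. This moved the median of all genes from 0.005 to 0.106 for the drug in wild type, from 0.01 to 0.10 for R6/2 against wild type on vehicle and from 0.01 to 0.12 for R6/2 on PLX3397 against wild-type vehicle, and by less in the other comparisons.

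On vehicle, the striatum of R6/2 mice had less RNA of medium spiny neurons, the projection neurons of the striatum, and more of interferon-stimulated genes than that of wild-type mice. Penk, the enkephalin precursor of indirect-pathway neurons (NCBI gene 18619; GRCm38 chromosome 4, 4133536 to 4138815, protein coding), was 8.54-fold lower (9.84 ± 0.47 against 6.75 ± 0.70 log2 CPM, SD). Irf7, a transcription factor of the interferon response (gene 54123; chromosome 7, 141263183 to 141266499, protein coding), was 5.88-fold higher (0.91 ± 0.33 against 3.46 ± 0.24 log2 CPM, SD). Homeostatic microglial genes showed no called change.

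This comparison of R6/2 with wild type on vehicle asked what the mutation changes without the drug. Of 15397 genes, 325 were called (95 higher, 230 lower; 3476 at an unadjusted p under 0.05), and 689 with the GC and length trend removed (382 higher, 307 lower). The count was not stable to the loss of 1 library, which also makes the fit smaller. It was 1 without wild-type vehicle library 1 and 1 without library 2 of that group. Without R6/2 vehicle libraries 1, 2 and 3 it was 79, 2 and 51. It was 561 and 162 without wild-type PLX3397 libraries 1 and 3.

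Among striatal projection neuron genes, Penk fell by 3.09 ± 0.38 (limma adjusted p = 0.0161) and Pdyn, the dynorphin precursor of direct-pathway neurons, by 2.34 ± 0.40 (adjusted p = 0.0284). Scn4b, a sodium channel subunit, fell by 3.87 ± 0.70 (adjusted p = 0.0310), and Ryr1, an intracellular calcium release channel, by 3.64 ± 0.51 (adjusted p = 0.0161). Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, fell by 2.50 ± 0.54 (adjusted p = 0.0444). The dopamine receptors Drd1 and Drd2 did not pass the threshold (adjusted p = 0.0681 and 0.0523; ranges over the alternatives 0.0440 to 0.253 and 0.0401 to 0.214), and both did after the GC and length trend was removed or without wild-type vehicle library 3 (0.0440 and 0.0401). Drd2 was also called without wild-type PLX3397 library 1 (0.0411) or 2 (0.0494) or R6/2 PLX3397 library 1 (0.0430). Of 37 measured medium spiny neuron genes, 11 were lower, 34 when adjusted over the list alone, with a list median of -1.76. The list test, camera, gave adjusted p = 1.23e-21, and 0.304 with an estimated correlation. The markers of D2-type neurons had a median of -2.44 (camera adjusted p = 1.74e-07; 0.304 with an estimated correlation) and those of D1-type neurons one of -1.42 (camera adjusted p = 1.08e-05; 0.304 with an estimated correlation).

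Interferon-stimulated genes rose as a list: 10 of 29 measured were higher and 24 when adjusted over the list alone, with a list median of 1.04 (camera adjusted p = 4.63e-19; 0.232 with an estimated correlation). Irf7 rose by 2.56 ± 0.23 (limma adjusted p = 0.00368) and Usp18, a protease that takes the ubiquitin-like protein Isg15 off other proteins, by 2.22 ± 0.37 (adjusted p = 0.0238). Antigen presentation genes had a median of 0.82 with 0 of 16 called by limma and 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.05e-04; 0.447 with an estimated correlation).

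Of the called genes in this pair of groups, Irf7 kept its call in all 24 alternatives. Penk, Ryr1, Rasgrp2 and Msmo1 lost theirs without wild-type vehicle library 1 or 2 or R6/2 vehicle library 2, and Penk then had adjusted p = 0.0980, 0.0856 and 0.0597 (range over the alternatives 0.0114 to 0.0980). Rasgrp2 (0.0508) and Msmo1 (0.0544) also lost theirs without R6/2 vehicle library 3. So did Pdyn (0.0721) without library 1, and Scn4b (0.0755 and 0.0572) and Usp18 (0.0521 and 0.0516) without either. These 3 also did without the 3 libraries named first. Over the alternatives these adjusted p reached from 0.0172 to 0.122 for Rasgrp2 and Msmo1, 0.0206 to 0.128 for Pdyn, 0.0213 to 0.140 for Scn4b and 0.0170 to 0.128 for Usp18. Ppp1r1b kept its call in 13 of 24 alternatives (0.0269 to 0.193) and lost it without any 1 of wild-type vehicle libraries 1 (0.178) and 2 (0.193), wild-type PLX3397 library 3 (0.0631), R6/2 vehicle libraries 1 (0.115), 2 (0.143) and 3 (0.0639) and R6/2 PLX3397 library 3 (0.0556). Rasgrp2, which activates the small GTPase Rap1, had fallen by 2.28 ± 0.36 (limma adjusted p = 0.0232).

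Further lists changed between the genotypes on vehicle. Immediate early genes, which neuronal activity induces, had a median of -0.74 (camera adjusted p = 0.000403; 0.467 with an estimated correlation), with 2 of 20 lower, Egr2 and Npas4, and 3 when adjusted over the list alone. Striatal interneuron genes had a median of -1.17 with 4 of 17 lower and 7 when adjusted over the list alone (camera adjusted p = 5.60e-05; 0.129 with an estimated correlation), among them the choline transporter Slc5a7 and the acetylcholine synthase Chat. Astrocyte genes (median -0.50, camera adjusted p = 3.92e-06; 0.304 with an estimated correlation) included Gja1, the gap junction protein of astrocytes, and the glutamate transporter Slc1a3 among 3 of 21 that were lower, against 8 lower and 1 higher when adjusted over the list alone. Cholesterol synthesis genes had a median of -0.31 with 3 of 25 lower, 9 when adjusted over the list alone (camera adjusted p = 5.25e-05; 0.304 with an estimated correlation). Msmo1, a sterol oxidase, fell by 0.88 ± 0.14 (limma adjusted p = 0.0222). Myelin genes had a median of -0.59 with 2 of 21 lower, 9 when adjusted over the list alone (camera adjusted p = 3.92e-06; 0.467 with an estimated correlation), among them Ugt8a, which makes the myelin lipid galactosylceramide. Glutamate receptor genes had a median of -0.54, with 1 of 27 lower and 4 when adjusted over the list alone (camera adjusted p = 0.000458; 0.467 with an estimated correlation; 0.0790 without R6/2 vehicle library 1 and 0.0768 without both libraries high in choroid plexus genes, over a range of 3.72e-05 to 0.0790). Genes of the thalamus, septum and pallidum, which border the striatum, had a median of -1.01 with 2 of 12 lower, 6 when adjusted over the list alone (camera adjusted p = 0.000534; 0.467 with an estimated correlation). Without R6/2 vehicle library 2, the adjusted p was 0.103 for Egr2, 0.0939 for Slc5a7 and 0.120 for both Chat and Gja1. These calls also ended without wild-type vehicle library 1 (0.122 to 0.160) or 2 (0.107 to 0.170) or R6/2 vehicle library 1 (0.0576 to 0.0965). Those of Egr2 (0.0711), Chat (0.0519) and Gja1 (0.0619) ended without R6/2 vehicle library 3 and that of Chat (0.0565) without wild-type PLX3397 library 3. Their ranges over the alternatives were 0.0243 to 0.149 for Egr2, 0.0142 to 0.122 for Slc5a7, 0.0321 to 0.170 for Chat and 0.0180 to 0.156 for Gja1.

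The largest rises and falls in this comparison included genes with few reads. Pax2 and Pou4f1, transcription factors of neural development, had 188, 40 and 27 reads and 80, 90 and 43 reads in the R6/2 vehicle libraries, against 0 to 1 and 0 to 2 in the wild-type ones. Twist1, a mesenchymal transcription factor, had 154, 68 and 31 reads against 1, 2 and 3. Espn, which bundles actin, and Crybb3, a lens crystallin, rose by 2.43 ± 0.46 and 2.43 ± 0.43 (limma adjusted p = 0.0320 and 0.0296). Among the falls, Epyc, a small matrix proteoglycan, had 0, 3 and 2 reads in R6/2 against 265, 96 and 29, and Gpx6, a glutathione peroxidase, 0, 2 and 4 against 63, 123 and 24. Eomes, Ptpn7 and Gbx1 were the other large falls next to Scn4b. Each of these calls ended without wild-type vehicle library 1, library 2 or R6/2 vehicle library 2: for Pou4f1 the adjusted p was then 0.101, 0.0856 and 0.0699, over a range of 0.00703 to 0.101.

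Few matrix and net genes had a called change with genotype on vehicle. Hapln1, the link protein that ties proteoglycans to hyaluronan (gene 12950; chromosome 13, 89540529 to 89611832, protein coding), was 3.76-fold lower (log2 change -1.91 ± 0.33, limma adjusted p = 0.0274; range over the alternatives 0.0158 to 0.128). Its call ended without wild-type vehicle libraries 1 (0.128) or 2 (0.127) or R6/2 vehicle libraries 1 (0.0694), 2 (0.0940) or 3 (0.0572). The aggrecan gene Acan and the tenascin gene Tnr showed no called change. Of 30 perineuronal net genes, 1 was lower and, adjusted over the list alone, 1 was higher and 4 lower (median -0.26, camera adjusted p = 0.187). Of 37 other matrix genes, such as collagens and laminins, 0 were called by limma, and 1 was higher and 3 lower when adjusted over the list alone (median 0.24, camera adjusted p = 0.254). Csf1r and Tmem119, a surface protein specific to microglia, differed by 0.18 ± 0.68 and 0.18 ± 0.26 (adjusted p = 0.900 and 0.717), and 0 of 32 homeostatic microglial genes were called by limma (0 when adjusted over the list alone; median 0.01, camera adjusted p = 0.900). The SE pools the spread of all 4 groups, which for these genes was wider on PLX3397. The mean of this list was 4.12 ± 0.12 log2 CPM in wild type and 4.14 ± 0.27 in R6/2 on vehicle (SD). On PLX3397 its SD was 0.70 and 0.55. A small difference on vehicle in a single microglial gene could therefore go uncalled.

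**Figure D1:**
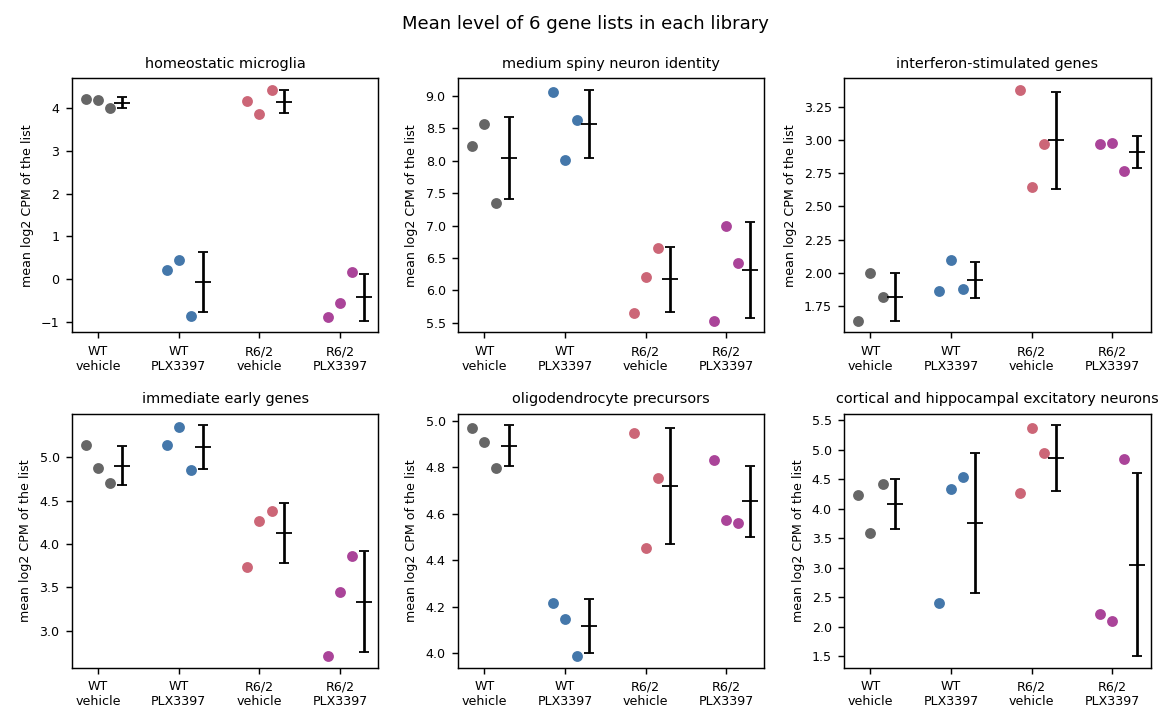
Mean log2 CPM of 6 gene lists in each library, for wild-type and R6/2 mice on vehicle or PLX3397 (points, libraries; bars, mean ± SD, n = 3 per group). The homeostatic microglial list stood at 4.12 and 4.14 on vehicle and at -0.07 and -0.42 on PLX3397.

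In wild-type mice, PLX3397 removed nearly all microglial RNA, and genes of oligodendrocyte precursors and several perineuronal net genes were lower. The net genes did not pass as a list. Csf1r, the drug's target (gene 12978; chromosome 18, 61105572 to 61131139, protein coding), went from 6.66 ± 0.07 to 0.71 ± 1.52 log2 CPM (SD), with 1.62% left. Vcan and Tnr, which encode the net proteins versican and tenascin-R, were 3.62-fold and 3.47-fold lower.

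This comparison asked what the drug does in a striatum without the mutation. The drug changed 2191 genes (913 higher, 1278 lower; 5246 at an unadjusted p under 0.05), and 1539 with the GC and length trend removed (1050 higher, 489 lower), of which 818 were called in the same direction in both. The count was 228, 242 and 935 without wild-type vehicle library 1, wild-type vehicle library 2 and wild-type PLX3397 library 2.

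Homeostatic microglial genes fell, with 28 of 32 called, 30 when adjusted over the list alone (median -4.92, which left 3.29%; camera adjusted p = 5.72e-31; 0.240 with an estimated correlation). The fractalkine receptor Cx3cr1 fell by 6.00 ± 0.60 (limma adjusted p = 0.000431), the purine receptor P2ry12 by 5.83 ± 0.39 (adjusted p = 3.25e-05), Csf1r by 5.95 ± 0.68 (adjusted p = 7.54e-04) and Tmem119 by 4.87 ± 0.26 (adjusted p = 1.49e-05). C1qc, Siglech and P2ry13, a complement subunit, a lectin and a purine receptor of microglia, were the other large falls. These 7 genes kept their calls in all 24 alternatives. Genes of border macrophages, which sit along vessels and meninges, had a median of -1.47 with 3 of 6 lower (3 when adjusted over the list alone; camera adjusted p = 0.0102; 0.544 with an estimated correlation), among them the mannose receptor Mrc1. The complement list had 7 of 15 lower and 1 higher, 7 and 2 when adjusted over the list alone (median -0.41, camera adjusted p = 0.0102; 0.555 with an estimated correlation): C1qa, C1qb and C1qc were among the falls, and C1s1, a complement protease, was the rise. That list was not called without both libraries high in choroid plexus genes (0.0619; range 0.000868 to 0.0619). C1qa, C1qb, C1qc and Itgam are on both the complement and the microglial list. The Csf1r ligands Csf1 (0.01, limma adjusted p = 0.988) and Il34 (0.60 ± 0.19, adjusted p = 0.0558) did not change by a called amount.

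Oligodendrocyte precursor genes had a median of -0.78 with 7 of 16 lower, 9 when adjusted over the list alone (camera adjusted p = 1.30e-04; 0.544 with an estimated correlation). The growth factor receptor Pdgfra fell by 1.46 ± 0.22 (limma adjusted p = 0.00420), Gpr17, a receptor that times their maturation, by 1.33 ± 0.15 (adjusted p = 0.000734), and the transcription factor Sox6 by 1.42 ± 0.22 (adjusted p = 0.00549). All 3 calls held in the 24 alternatives. Genes of the thalamus, septum and pallidum had a median of -1.41 with 0 of 12 called by limma and 0 when adjusted over the list alone (camera adjusted p = 0.0204; 0.903 with an estimated correlation). That list was not called without wild-type vehicle library 2 (0.0791) or 3 (0.0522), wild-type PLX3397 library 1 (0.0796) or 3 (0.0826) or both libraries high in choroid plexus genes (0.0811), over a range of 0.00185 to 0.0826.

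Perineuronal net genes did not pass as a list on PLX3397 in wild type (camera adjusted p = 0.117; median -0.34), with 7 of 30 lower and 2 higher, 9 and 2 when adjusted over the list alone. Versican (Vcan; gene 13003; chromosome 13, 89655309 to 89743027, protein coding) fell by 1.86 ± 0.40 (limma adjusted p = 0.0172; range over the alternatives 0.0128 to 0.0798), from 5.18 ± 0.67 to 3.32 ± 0.55 log2 CPM (SD). Tnr (gene 21960; chromosome 1, 159523729 to 159931729, protein coding) fell by 1.79 ± 0.43 (adjusted p = 0.0248; range 0.0116 to 0.106). Ptprz1, the receptor phosphatase whose shed form is the proteoglycan phosphacan, fell by 1.66 ± 0.22 (adjusted p = 0.00237; range 0.00147 to 0.0221) and kept its call in all 24 alternatives, with a change of -0.71 after the GC and length trend was removed. Aggrecan (Acan; gene 11595; chromosome 7, 79053226 to 79115099, protein coding) fell by 0.88 ± 0.26 (adjusted p = 0.0478; range 0.0449 to 0.171) and Hapln1 by 1.11 ± 0.33 (adjusted p = 0.0454; range 0.0201 to 0.260), and these calls held in 6 and 7 of 24 alternatives. With the GC and length trend removed Hapln1 changed by -0.42 (adjusted p = 0.260). Brevican (Bcan, 0.17 ± 0.16) and neurocan (Ncan, -0.02 ± 0.31) showed no called change. Cspg4 and Cspg5 are on both the net and the precursor list. Cell types were not separated, so whether net genes fell independently of the precursor genes was not tested. Chpf, an enzyme that lengthens chondroitin chains, rose by 0.70 ± 0.14 (adjusted p = 0.0140; range 0.0104 to 0.0712). Of the 37 other matrix genes 0 were called by limma and 0 when adjusted over the list alone (median -0.09, camera adjusted p = 0.506).

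Leaving out wild-type vehicle library 1 or 2 ended the calls of Vcan (adjusted p = 0.0798 and 0.0732), Tnr (0.106 and 0.0949), Chpf (0.0712 and 0.0667), Acan (0.0677 and 0.171) and Hapln1 (0.168 and 0.136). Tnr (0.0703), Acan (0.0866) and Hapln1 (0.0966) also lost theirs without wild-type PLX3397 library 2, and Acan (0.0955) and Hapln1 (0.0938) without library 1 of that group. Acan lost its call without wild-type vehicle library 3 (0.0982), and leaving out any R6/2 library, except R6/2 vehicle library 1 for Acan, ended both the Acan and the Hapln1 call (0.0509 to 0.0688). The ranges over all the alternatives were 0.0128 to 0.0798 for Vcan, 0.0116 to 0.106 for Tnr, 0.0104 to 0.0712 for Chpf, 0.0449 to 0.171 for Acan and 0.0201 to 0.260 for Hapln1.

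**Figure D2:**
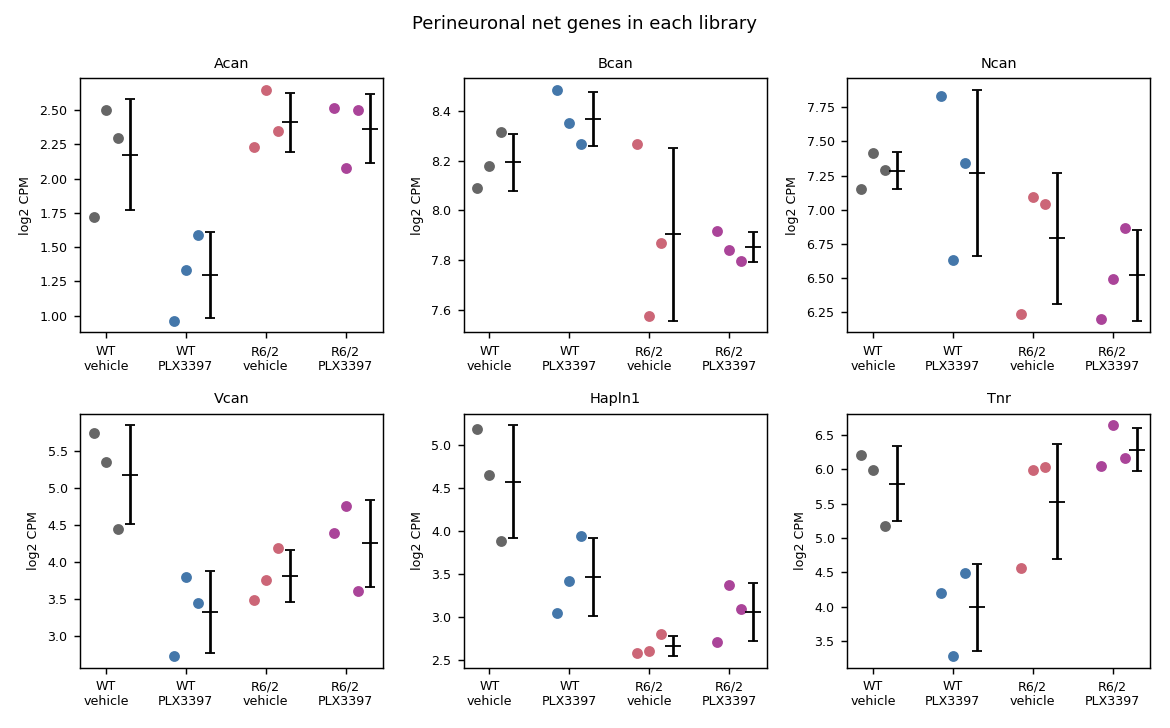
Log2 CPM of 6 perineuronal net genes (Acan, Bcan, Ncan, Vcan, Hapln1 and Tnr) in each library of the 4 groups (points, libraries; bars, mean ± SD, n = 3 per group). In wild type, Vcan was at 5.18 on vehicle and 3.32 on PLX3397, and in R6/2 at 3.80 and 4.25.

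Genes of oxidative phosphorylation rose in wild-type mice on PLX3397, with 10 of 34 higher and 1 lower (17 and 1 when adjusted over the list alone; median 0.49, camera adjusted p = 1.01e-07; 0.796 with an estimated correlation). Ndufs3, a subunit of respiratory complex I, rose by 0.74 ± 0.13 (limma adjusted p = 0.0111), and without wild-type vehicle library 1 its adjusted p was 0.0594 (range over the alternatives 0.00558 to 0.0594). The list's fall was Ppargc1a, a coactivator of mitochondrial genes. Heat shock and stress response genes had a median of 0.37 with 6 of 25 higher, 6 when adjusted over the list alone (camera adjusted p = 0.00132; 0.796 with an estimated correlation), among them Asns, an asparagine synthetase that does not fold proteins. Medium spiny neuron genes had a median of 0.60 with 0 of 37 called by limma and 0 when adjusted over the list alone (camera adjusted p = 0.0134; 0.903 with an estimated correlation). That list was not called without wild-type vehicle library 3 (0.480), without wild-type PLX3397 library 1 (0.254), without both libraries high in choroid plexus genes (0.265) or with the GC and length trend removed (0.131), over a range of 7.17e-05 to 0.480. Xlr3b, an X-linked nuclear protein, had the largest rise, 2.70 ± 0.45 (limma adjusted p = 0.00698), and kept its call in all 24 alternatives. Depp1, induced by fasting and hypoxia, Tnni1, a troponin, Prr22, and the endothelial genes Vwf and Icam2 followed, and the calls of Depp1 and Vwf held in 8 and 6 of 24 alternatives.

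**Figure D3:**
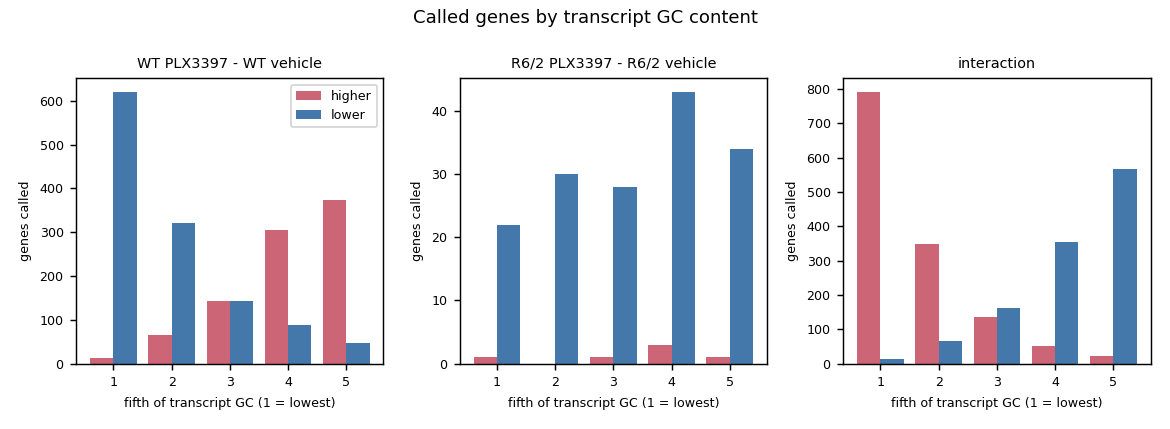
Number of genes called higher or lower in each of 5 equal bins of transcript GC content for PLX3397 in wild type, PLX3397 in R6/2 and the difference between these 2 drug effects (bars, genes; y scales differ between panels). For PLX3397 in wild type, 14 genes were called higher and 620 lower in the bin of lowest GC, and 374 higher and 47 lower in the highest.

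In R6/2 mice, PLX3397 likewise removed microglial RNA, and few other genes had a called change. Csf1r went from 6.84 ± 0.28 to 0.12 ± 1.13 log2 CPM (SD), with 0.948% left. Interferon-stimulated genes stayed at the R6/2 level, and none of Acan, Vcan, Hapln1 and Tnr had a called change.

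This comparison asked what the drug does in the presence of the mutation. It had 169 called genes (9 higher, 160 lower; 2023 at an unadjusted p under 0.05), and 167 with the GC and length trend removed (10 higher, 157 lower). Without R6/2 PLX3397 library 3 the count was 381, and without both R6/2 PLX3397 libraries that were low in cortical genes, which left 1 library in that group, it was 58.

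Of 32 homeostatic microglial genes, 29 fell, 31 when adjusted over the list alone (median -5.11, which left 2.89%; camera adjusted p = 6.35e-65; 0.0268 with an estimated correlation). Cx3cr1 fell by 6.88 ± 0.60 (limma adjusted p = 0.000165), Csf1r by 6.72 ± 0.68 (adjusted p = 0.000398), Tmem119 by 6.05 ± 0.26 (adjusted p = 1.43e-06) and P2ry12 by 4.83 ± 0.39 (adjusted p = 0.000103). The activated microglia list had a median of -0.47 with 5 of 18 lower, 8 when adjusted over the list alone (camera adjusted p = 1.76e-08; 0.146 with an estimated correlation). Trem2, a lipid receptor of microglia, fell by 6.11 ± 0.61 (limma adjusted p = 0.000398). Complement genes had a median of -0.65 with 6 of 15 lower, 6 when adjusted over the list alone (camera adjusted p = 4.46e-07; 0.132 with an estimated correlation). Border macrophage genes had a median of -0.86 with 2 of 6 lower, 3 when adjusted over the list alone (camera adjusted p = 0.0286; 0.455 with an estimated correlation). Mrc1 fell by 4.48 ± 0.41 (limma adjusted p = 0.000257). Cytokine genes had a median of -0.33 with 2 of 11 lower, Il16 and Tgfb1, and 3 when adjusted over the list alone (camera adjusted p = 0.000485; 0.178 with an estimated correlation). Antigen presentation genes had a median of -0.50 with 1 of 16 lower, Cd74, and 2 when adjusted over the list alone (camera adjusted p = 0.00172; 0.513 with an estimated correlation). The Cd74 call held in 4 of 24 alternatives. Over the alternatives the median of the cytokine list ran from -0.488 to -0.0505. The border macrophage list was not called without R6/2 vehicle library 1 (0.0536) or 3 (0.0593) or R6/2 PLX3397 library 3 (0.147) or both libraries high in choroid plexus genes (0.0590), over a range of 5.96e-05 to 0.147. Among genes with a mean CPM of at least 1 it was not called either (0.112), and its median was 0.25. The antigen presentation list was not called without R6/2 vehicle library 1 (0.0601) or both choroid-high libraries (0.0590), over a range of 1.44e-07 to 0.0601.

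Interferon-stimulated genes showed no change with PLX3397 in R6/2: the median was 0.00, 0 of 29 were called by limma and camera gave adjusted p = 0.524. The mean of the list was 3.00 ± 0.37 log2 CPM in R6/2 on vehicle and 2.91 ± 0.12 on PLX3397, against 1.82 ± 0.18 and 1.95 ± 0.13 in wild type (SD). Of 30 perineuronal net genes, 0 were called by limma and 0 when adjusted over the list alone (median -0.04, camera adjusted p = 0.796), and the 37 other matrix genes gave 0 in both counts as well (median -0.20, camera adjusted p = 0.169). Vcan changed by 0.44 ± 0.40, Hapln1 by 0.39 ± 0.33, Tnr by 0.75 ± 0.43 and Acan by -0.05 ± 0.26, none past the limma threshold (adjusted p = 0.622, 0.594, 0.463 and 0.948). Immediate early genes had a median of -0.81 (camera adjusted p = 1.84e-06; 0.418 with an estimated correlation) with 1 of 20 lower, Dusp6, a phosphatase that turns off ERK, and 3 when adjusted over the list alone. The median ran from -1.15 to -0.19 over the alternatives, and the list stood at 2.71, 3.45 and 3.86 log2 CPM in R6/2 PLX3397 libraries 1 to 3, against 3.73 to 4.38 on vehicle. The Dusp6 call held in 11 of 24 alternatives.

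The calls of genes that rose in R6/2 on PLX3397 depended on single libraries. Trh, a hormone precursor of hypothalamic and other neurons, had 993, 417 and 281 reads in the R6/2 PLX3397 libraries against 115, 14 and 28 on vehicle (3.54 ± 0.65, limma adjusted p = 0.0220). Lhx8, a transcription factor of basal forebrain cholinergic neurons, had 528, 393 and 162 reads against 31, 9 and 67 (3.33 ± 0.61, adjusted p = 0.0217). Isl1, a transcription factor of direct-pathway and cholinergic neurons, rose by 1.35 ± 0.24 (adjusted p = 0.0177), and AI606473, the homeobox gene Gbx1 and the protocadherin Pcdh11x were the other large rises. Without R6/2 PLX3397 library 1 or library 2 none of these 6 rises was called: the adjusted p was 0.121 and 0.0756 for Trh, 0.127 and 0.112 for Lhx8 and 0.0834 and 0.0771 for Isl1. Leaving out R6/2 vehicle library 2 ended these 3 calls as well (0.0851, 0.0607 and 0.0851), library 1 of that group ended those of Lhx8 (0.0873) and Isl1 (0.0860), and library 3 that of Trh (0.101). Over the alternatives the adjusted p reached from 0.00867 to 1.00 for Trh, 0.00558 to 1.00 for Lhx8 and 0.00589 to 1.00 for Isl1. Genes of cortical and hippocampal neurons had a median of -1.75 with 0 of 15 called by limma and 6 lower when adjusted over the list alone (camera adjusted p = 0.000485; 0.513 with an estimated correlation). Without R6/2 PLX3397 libraries 1 and 2, which left 1 library in that group, the list was not called (median -0.22, adjusted p = 0.823, with camera's direction up; range over the alternatives 4.52e-07 to 0.886). With the mean of this same list as a covariate it was not called either (0.886), as follows from that fit. Genes of the thalamus, septum and pallidum had a median of 1.01 with 1 of 12 higher, 2 when adjusted over the list alone (camera adjusted p = 0.00295; 0.532 with an estimated correlation; 0.0653 without R6/2 PLX3397 library 1, 0.144 with the cortical covariate and 0.473 without R6/2 PLX3397 libraries 1 and 2, over a range of 7.19e-05 to 0.473). Genes of direct-pathway (D1) neurons, a list that was lower in R6/2 on vehicle, had a median of 0.46 with 1 of 12 higher, Isl1, and 1 when adjusted over the list alone (camera adjusted p = 0.00295; 0.501 with an estimated correlation). That list stood at 4.20 ± 0.32 log2 CPM in R6/2 on vehicle and 4.93 ± 0.47 on PLX3397, against 5.51 ± 0.21 in wild type on vehicle (SD). It was not called without R6/2 PLX3397 library 2 (0.0510, over a range of 9.22e-05 to 0.0510). Its median ran from 0.179 to 0.876 over the alternatives. The list stood at 4.60, 5.47 and 4.72 log2 CPM in R6/2 PLX3397 libraries 1 to 3.

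With microglia depleted in both genotypes, R6/2 striatum again had less medium spiny neuron RNA and more interferon-stimulated RNA than wild-type striatum. Penk was 10.3-fold lower, Drd2, the dopamine receptor of indirect-pathway neurons, 7.79-fold lower and Irf7 2.52-fold higher. Acan and Tnr were 2.10-fold and 4.89-fold higher in R6/2.

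This comparison of R6/2 with wild type on PLX3397 asked what the mutation changes when microglia are gone, and it had 5389 called genes (2637 higher, 2752 lower; 7174 at an unadjusted p under 0.05). With the GC and length trend removed 3855 were called (1872 higher, 1983 lower), and without R6/2 PLX3397 libraries 1 and 2, which left 1 library in that group, 237. Leaving out library 1 alone gave 3383 and library 2 alone 3461.

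Medium spiny neuron genes had a median of -2.36 with 30 of 37 lower, 31 when adjusted over the list alone (camera adjusted p = 3.22e-12; 0.706 with an estimated correlation). Penk fell by 3.36 ± 0.38 (limma adjusted p = 0.000450) and Ppp1r1b by 3.62 ± 0.54 (adjusted p = 0.00122), and both calls held in all 24 alternatives. Drd1 was lower by 2.62 ± 0.60 (adjusted p = 0.00809), Drd2 by 2.96 ± 0.57 (adjusted p = 0.00379) and the adenosine receptor Adora2a by 3.60 ± 0.61 (adjusted p = 0.00216). Interferon-stimulated genes had a median of 1.07 with 18 of 29 higher, 19 when adjusted over the list alone (camera adjusted p = 1.84e-06; 0.648 with an estimated correlation). Irf7 rose by 1.33 ± 0.23 (limma adjusted p = 0.00226). Immediate early genes had a median of -1.60 with 17 of 20 lower, 17 when adjusted over the list alone (camera adjusted p = 3.28e-07; 0.541 with an estimated correlation). Arc, which acts at synapses after activity, fell by 2.64 ± 0.41 (limma adjusted p = 0.00146). Cholesterol synthesis genes had a median of -0.61 with 16 of 25 lower and 2 higher, 18 and 2 when adjusted over the list alone (camera adjusted p = 1.29e-04; 0.541 with an estimated correlation).

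Perineuronal net genes moved both ways between the genotypes on PLX3397, with 7 of 30 higher and 6 lower, the same counts when adjusted over the list alone (median 0.09, camera adjusted p = 0.847). Acan was higher by 1.07 ± 0.26 (limma adjusted p = 0.0113), Tnr by 2.29 ± 0.43 (adjusted p = 0.00341) and Ptprz1 by 1.27 ± 0.22 (adjusted p = 0.00248), with group means of 1.30 ± 0.31 and 2.37 ± 0.25 log2 CPM (SD) for Acan. Bcan was lower by 0.51 ± 0.16 (adjusted p = 0.0281), but higher by 0.03 after the GC and length trend was removed (adjusted p = 0.883; range over the alternatives 0.00881 to 0.883). Without any 1 of wild-type PLX3397 libraries 1 (0.0652) and 2 (0.0556) and R6/2 PLX3397 libraries 1 (0.0578), 2 (0.0741) and 3 (0.0691), Bcan was not called. With R6/2 PLX3397 library 3 as the only one of its group, Acan and Tnr were higher by 1.21 and 2.17 and not called (adjusted p = 0.128 and 0.107, the highest of ranges that began at 0.0103 and 0.00133). Of the 37 other matrix genes 3 were higher and 2 lower, 2 and 2 when adjusted over the list alone (median 0.09, camera adjusted p = 0.702). Oligodendrocyte precursor genes had a median of 0.64 with 8 of 16 higher and 1 lower, the same counts when adjusted over the list alone (camera adjusted p = 0.0347; 0.744 with an estimated correlation), and were not called without wild-type PLX3397 library 3 (0.111) or R6/2 PLX3397 library 1 (0.0757) or with the cortical covariate (0.0671), over a range of 0.00143 to 0.111.

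The largest rises in this comparison were Pgr15l, Gabrq, Aff2, Gucy2f, Minar1 and Pou4f1, and the largest falls Gpx6, Ptpn7, Cd4, Fgf3, Egr2 and Lrrc10b. Minar1, a membrane protein that binds Notch2, rose by 3.70 ± 0.34 (limma adjusted p = 1.66e-04), and Lrrc10b, a leucine-rich repeat protein found in the striatum, fell by 4.80 ± 0.73 (adjusted p = 0.00127). Both kept their calls in all 24 alternatives.

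Across the 15397 genes, which are not independent replicates, the genotype change on PLX3397 and that on vehicle, taken from separate libraries, had Pearson's r = 0.148 and Spearman's rho = 0.0686. Without R6/2 PLX3397 library 2 or 3, r was 0.249 or 0.0557, and with the GC and length trend removed it was 0.313. Of the genes called in both, 52 were higher in both, 145 lower in both and 7 opposed, where independent lists would share 16.3, 41.1 and 56.4.

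R6/2 mice on PLX3397, set against wild-type mice on vehicle to ask how far treated mutants stood from healthy controls, lacked microglial RNA, had lower medium spiny neuron genes and had higher interferon-stimulated genes. Irf7 was 4.08-fold higher and Penk 5.09-fold lower. Egr2, an activity-induced transcription factor, was 28.0-fold lower.

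Here 702 genes were called (143 higher, 559 lower; 3166 at an unadjusted p under 0.05), and 1138 with the GC and length trend removed (623 higher, 515 lower). Leaving out wild-type vehicle library 1 or 2 gave 246 each, and R6/2 PLX3397 library 1 or 2 gave 294 or 388. Interferon-stimulated genes had a median of 0.91 with 14 of 29 higher, 21 when adjusted over the list alone (camera adjusted p = 5.03e-17; 0.0956 with an estimated correlation). Irf7 rose by 2.03 ± 0.23 (limma adjusted p = 6.82e-04) and kept its call in all 24 alternatives, and Usp18 rose by 2.52 ± 0.37 (adjusted p = 0.00314). Medium spiny neuron genes had a median of -1.65 with 14 of 37 lower, 31 when adjusted over the list alone (camera adjusted p = 1.80e-18; 0.203 with an estimated correlation). Genes of D1-type neurons (median -0.54, camera adjusted p = 0.0424; 0.487 with an estimated correlation) and interneurons (median -0.77, camera adjusted p = 0.0270; 0.160 with an estimated correlation) were lower too. The D1 list was not called without wild-type vehicle library 1 (0.0594) or 2 (0.0911), wild-type PLX3397 library 3 (0.0548), R6/2 vehicle library 1 (0.0501) or R6/2 PLX3397 library 1 (0.105) or 3 (0.163), over a range of 0.00198 to 0.163. The interneuron list was not called without wild-type vehicle library 3 (0.0628) or R6/2 PLX3397 library 3 (0.157), over a range of 0.000704 to 0.157. Penk fell by 2.35 ± 0.38 (limma adjusted p = 0.00612) and Egr2 by 4.80 ± 0.61 (adjusted p = 0.00139). Of the net genes 1 was called, Hapln1 (-1.52 ± 0.33, adjusted p = 0.0250), which held in 16 of 24 alternatives. Its call ended without wild-type vehicle library 1 (0.112) or 2 (0.104) or R6/2 PLX3397 library 1 (0.111) or 3 (0.0525), over a range of 0.00532 to 0.359. Homeostatic microglial genes had a median of -5.15 with 29 of 32 lower, 32 when adjusted over the list alone (camera adjusted p = 4.22e-49; 0.0645 with an estimated correlation).

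Of the genes called in R6/2 on vehicle, 7 were moved back by a called change with the drug. They changed one way with genotype on vehicle and the other way with PLX3397 in R6/2, and 0 changed the same way by limma. The 5 with names other than a model number were Gbx1, Lhx8, Isl1, the adhesion molecule Icam1 (1.46 with genotype, -1.41 with the drug) and the calcium channel subunit Cacna2d2 (-1.34 and 1.19). Both changes share the R6/2 vehicle libraries, so simulated data with no drug effect gave a mean of 0.09 such genes and at most 2. Independent lists of these sizes would share 1.12. Across all genes the 2 changes had a covariance of -0.170, against -0.0588 on average and -0.0670 at the lowest in the simulated data (r = -0.424, against -0.239 on average). The simulated noise was independent between genes, so it lacks shifts that many genes of a library share. These comparisons therefore cannot tell a drug effect from such shifts. Gbx1 is on the list of the thalamus, septum and pallidum, whose mean moved the same way: 3.14 log2 CPM in wild-type vehicle, 1.61 in R6/2 vehicle and 2.69 in R6/2 PLX3397. The count was 0 without wild-type vehicle library 1 or 2, R6/2 vehicle library 2 or R6/2 PLX3397 library 1 or 2, 2 without R6/2 vehicle library 1, 4 without wild-type vehicle library 3 or wild-type PLX3397 library 3, and 37 without R6/2 PLX3397 library 3.

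By the interaction test, the change with PLX3397 differed between R6/2 and wild-type libraries for many genes, among them some perineuronal net genes and genes of oligodendrocyte precursors, while microglial genes fell in both. Ptprz1 fell with PLX3397 in wild type, and the R6/2 change was higher by 2.23. Tnr differed by 2.55 ± 0.61 and Vcan by 2.30 ± 0.56 in the same direction.

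The interaction, which tests whether the drug's effect differed with genotype, was called for 2617 genes (1430 higher, 1187 lower; 5561 at an unadjusted p under 0.05), and for 952 with the GC and length trend removed (381 higher, 571 lower), with 534 shared. Without R6/2 PLX3397 libraries 1 and 2, which left 1 library in that group, it was called for 0 genes by limma. Leaving out 1 library gave 537 and 625 for wild-type vehicle 1 and 2, 1158 and 1668 for R6/2 vehicle 1 and 2, and 862 and 683 for R6/2 PLX3397 1 and 2. The 10 genes with the smallest p, all with limma adjusted p = 0.0139, were Minar1 (4.11 ± 0.48), N4bp2 (4.10 ± 0.54), the imprinted zinc finger gene Peg3 (3.44 ± 0.47), Dpy19l4 (3.34 ± 0.46), Enah, an actin regulator (1.66 ± 0.21), Ccdc85a (1.62 ± 0.20), the axon guidance gene Sema6d (1.35 ± 0.17), Ubald1 (-1.30 ± 0.17), Nat14 (-1.25 ± 0.15) and Ecsit, a complex I assembly factor (-1.08 ± 0.15). Of the alternatives, only the fit with 1 library left in the R6/2 PLX3397 group ended these 10 calls.

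For the net genes, 5 of 30 had a positive interaction (Vcan, Hapln1, Tnr, Ptprz1 and Csgalnact2) and 2 a negative one (Chst12 and Chpf), 6 and 3 when adjusted over the list alone (median 0.19, camera adjusted p = 0.310). The Tnr interaction (limma adjusted p = 0.0232; range over the alternatives 0.0206 to 0.244) was not called without wild-type vehicle library 1 (0.0651) or 2 (0.0605) or R6/2 PLX3397 library 2 (0.0608). That of Vcan (adjusted p = 0.0241; range 0.0151 to 0.274) was not called without wild-type vehicle library 1 (0.0658) or 2 (0.0630), R6/2 vehicle library 1 (0.0556) or R6/2 PLX3397 library 1 (0.0596) or 2 (0.0622), nor with the GC and length trend removed (1.67, adjusted p = 0.0600). Hapln1 (1.50 ± 0.46, adjusted p = 0.0467) kept its call in 7 of 23 alternatives and was 0.48 with the GC and length trend removed (adjusted p = 0.372; range 0.0203 to 0.372). Acan was not called (0.83 ± 0.37, adjusted p = 0.133). Tmem119 had an interaction of -1.18 ± 0.37 (adjusted p = 0.0489), with a call that held in 5 of 23 alternatives.

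As lists, oxidative phosphorylation (median -0.59, camera adjusted p = 7.79e-05), ribosomal proteins (-0.76, adjusted p = 1.17e-04), immediate early genes (-1.15, adjusted p = 0.00621), heat shock (-0.43, adjusted p = 0.0121), thalamus, septum and pallidum (2.67, adjusted p = 0.00528) and oligodendrocyte precursors (0.54, adjusted p = 0.0232) differed between the genotypes in their response by camera with the preset correlation only. Each had adjusted p = 0.818 with an estimated correlation, and fry called 0 of 36 lists. Over the alternatives the median ran from -1.38 to -0.457 for immediate early genes and from 1.38 to 3.35 for thalamus, septum and pallidum. Among the precursor genes 5 of 16 were called higher, and 6 higher and 1 lower when adjusted over the list alone. Of 34 oxidative phosphorylation genes 1 was higher and 7 lower, 1 and 15 when adjusted over the list alone, and of 25 heat shock genes 5 were lower in both counts. The heat shock call ended without wild-type PLX3397 library 3 (camera adjusted p = 0.0687) and with the GC and length trend removed (0.0765; range over the alternatives 0.00311 to 0.0765). The precursor call ended without that library (0.0687), without R6/2 vehicle library 2 (0.0585) and with the cortical covariate (0.0533; range 1.87e-04 to 0.0687). Across all genes the drug's change in R6/2 against that in wild type had Pearson's r = -0.106 and Spearman's rho = -0.517, and r was 0.106 after the GC and length trend was removed. Of the genes called for the drug in both genotypes, 135 were lower in both, 0 higher in both by limma and 2 opposed.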

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

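The tests of GC content and of a cortical covariate against the interaction were chosen only after the result was seen; the count over random groupings was planned before, and the shuffles of residuals were added last.

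A difference between the genotypes in the drug's effect brought each result here, by the limma interaction for genes and by camera for lists. It was called for 2617 genes. The list medians were -1.15 for immediate early genes, 0.54 for oligodendrocyte precursors, 2.67 for thalamus, septum and pallidum, -0.43 for heat shock, -0.59 for oxidative phosphorylation and -0.76 for ribosomal proteins. None of these lists was called with an estimated correlation or by fry.

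Among net and precursor genes the interaction was 2.30 for Vcan, 2.55 for Tnr, 1.50 for Hapln1, 2.23 for Ptprz1, -0.84 for Chpf, 1.24 for Pdgfra, 0.89 for Gpr17 and 2.03 for Sox6. Among neuronal and regional genes it was 1.39 for Isl1, 4.53 for Gbx1, 3.92 for Slc5a7, 3.84 for AI606473, 5.19 for Trh, 4.09 for Lhx8, 5.25 for Pcdh11x, 4.96 for Gabrq, 3.91 for Aff2 and 3.41 for Gucy2f. For immune, glial and vascular genes it was -1.23 for Irf7, -1.18 for Tmem119, -1.12 for Il34, 0.99 for Gja1, 1.66 for Slc4a4 and -1.79 for Icam2. Metabolic and other genes had -3.18 (Depp1), -1.48 (Prr22), -0.85 (Ndufs3), -0.90 (Ndufv1), 1.72 (Ppargc1a), -0.63 (Asns) and -1.12 (Dusp6). The 10 smallest p belonged to Minar1 (4.11), Nat14 (-1.25), Ccdc85a (1.62), Enah (1.66), Sema6d (1.35), N4bp2 (4.10), Ubald1 (-1.30), Ecsit (-1.08), Peg3 (3.44) and Dpy19l4 (3.34).

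The interaction ran against transcript GC (rho -0.553 across genes), and GC and length took up 32.4% of its variance. Of 2509 called genes with a known transcript, 21.3% kept their call when the GC and length trend was removed. The kept calls argue against the trend, as removed here, as the whole cause. The lost ones leave it open for most of the called genes. With the cortical covariate 32.6% of the calls were kept. That argues in the same way against the share of cortical tissue as the whole cause and leaves it open for the calls that were lost. The Vcan call ended with a smaller change once the GC trend was removed (2.30 before, 1.67 after, adjusted p = 0.0600; range over the alternatives 0.0151 to 0.274), so that trend stays open for it, while with the covariate its change was 2.20 (adjusted p = 0.0639) and the lost call says little about cortical tissue. Random groupings of the 12 libraries gave as many calls in 1 of 100, the real one, with 146 in the highest other, but these also mix the genotype and drug effects. Shuffled residuals of a fit without the interaction keep both effects. They gave as many in 1 of 100, again the real one, with 290 in the highest other. This argues against a random spread of single libraries, but 1 of 100 is the lowest share this test can give. A shift that follows the groups would pass it as well. The relation to transcript GC did follow the 2 groups on PLX3397. Levels less the gene mean had rho of 0.232 to 0.437 in wild-type PLX3397 libraries and -0.513 to -0.188 in R6/2 PLX3397 ones. On vehicle the groups overlapped. There rho was -0.345, -0.331 and 0.0537 in wild-type libraries 1 to 3 and 0.286, 8.4e-05 and 0.00386 in R6/2 ones. The thalamus, septum and pallidum list had means of 3.14 and 1.77 log2 CPM in wild type on vehicle and PLX3397. In R6/2 these were 1.61 and 2.69. Whether an uneven share of that neighbouring tissue gave part of the interaction, as for Gbx1 of that list, was not tested. A difference between genotypes in the response to the drug stays open. It was not tested apart from GC content, tissue of the cortex or of these regions, and shifts that follow the groups.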

How the results depend on the processing

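The alternatives with a GC and length trend removed, limma-voom, a cortical covariate and both sets of left-out libraries were chosen only after the results were seen; the others were planned.

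Of the values compared with other settings for single genes and lists, 5057 kept a call in the same direction or stayed uncalled, 752 lost their call, 23 gained one and 3 reversed. Direction was not compared for genes that stayed uncalled. The settings include the fit with no filter, which was identical to the main one. For counts and relations 161 stayed, while 55 counts fell and 8 rose by more than 1.5 times, 13 relations moved and 3 reversed. The interferon and medium spiny neuron lists kept their calls in all 23 alternatives in R6/2 against wild type on vehicle, on PLX3397, and on PLX3397 against wild-type vehicle (interferon medians 0.88 to 1.25, 0.75 to 1.12 and 0.74 to 1.06). All of these used camera's preset correlation, and none of these calls held with an estimated correlation.

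Counts of called genes moved as follows, and the cause was not tested except that smaller fits hold fewer libraries and that leaving out R6/2 PLX3397 libraries 1 and 2 left 1 library in that group, assumed to vary like the others, so that fewer calls there say nothing about those libraries. For R6/2 against wild type on vehicle (325) the count was 689 with the GC and length trend removed, 145 with limma-voom, 80 with the cortical covariate and 103 without both libraries high in choroid plexus genes. For PLX3397 in wild type (2191) it was 351 in a fit of 6 libraries, 1317 without R6/2 PLX3397 libraries 1 and 2 and 3560 without the choroid-high libraries. For PLX3397 in R6/2 (169) it was 98 in 6 libraries, 102 with the covariate and 58 without R6/2 PLX3397 libraries 1 and 2. For R6/2 against wild type on PLX3397 (5389) it was 2934 in 6 libraries and 237 without those libraries. For R6/2 on PLX3397 against wild-type vehicle (702) it was 1138, 91 and 1123 with the trend removed, without those libraries and without the choroid-high ones. For the interaction (2617) it was 952 with the trend removed, 872 with the covariate and 0 by limma without R6/2 PLX3397 libraries 1 and 2.

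The 7 genes moved back became 12 with the trend removed, 2 with limma-voom, 2 without the choroid-high libraries, and 0 by limma in 6 libraries, with the covariate and without R6/2 PLX3397 libraries 1 and 2. The genotype relation across genes (r = 0.148) was 0.313, 0.348 and 0.203 with the trend removed, without R6/2 PLX3397 libraries 1 and 2 and without the choroid-high libraries. The drug relation (r = -0.106) was -0.314 and -0.0124 with pseudocounts of 1 and 0.01, -0.0417 with limma-voom and -0.0620 with the covariate, and it reversed to 0.106, 0.0890 and 0.00690 in the same 3 settings. Of 216 list tests 74 were called, 1 with an estimated correlation and 49 with fry. The cause of these moves was not tested.

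Leaving out 1 library at a time gave 1 to 561 genes for R6/2 against wild type on vehicle, 228 to 2716 for PLX3397 in wild type, 125 to 381 for PLX3397 in R6/2, 3383 to 5630 for the genotypes on PLX3397, 246 to 931 for R6/2 on PLX3397 against wild-type vehicle and 537 to 3532 for the interaction. It gave 0 to 37 genes moved back, r from 0.0557 to 0.249 for the genotype relation and from -0.159 to -0.0366 for the drug relation, and 73 to 96 called lists.

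The median of mitochondrially encoded transcripts in R6/2 on vehicle reversed from -0.69 to 0.22 with the trend removed (adjusted p = 0.671). Bcan between the genotypes on PLX3397 reversed from -0.51 to 0.031 with it (adjusted p = 0.883; range over the alternatives 0.00881 to 0.883), and the cause was not tested. The cortical list for PLX3397 in R6/2 went from -1.75 to a median of -0.22 without R6/2 PLX3397 libraries 1 and 2, where camera's direction was up (adjusted p = 0.823).

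The replicate numbers did not pair the libraries: 3 of 18 same-number pairs correlated above 0.1 (r from -0.321 to 0.396) and 1 of 12 libraries correlated best with its own number. With the number as a block the counts were 40, 1110, 409 and 1432 for R6/2 against wild type on vehicle, PLX3397 in wild type, R6/2 on PLX3397 against wild-type vehicle and the interaction, and 1 gene was moved back. The planned sex covariate was not run: Xist is not in the table, and the 4 Y-linked genes in it had at least 79 reads in every library, so no library without Y-linked reads was seen. The fit with no filter was identical, as the planned filter removed no gene. Depth limits genes with few reads, such as Pax2 with 0 to 1 read per wild-type vehicle library.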

Other observations

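The tests of the interferon rise and of the cortical genes below were chosen only after the results were seen; the counts over other splits were planned.

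Further lists were called against wild type on vehicle in R6/2 mice. Genes of endothelial cells and pericytes had a median of 0.61 (camera adjusted p = 5.44e-05; 0.467 with an estimated correlation), and mitochondrially encoded transcripts one of -0.69 (camera adjusted p = 0.00268; 0.467 with an estimated correlation), which turned to 0.22 with the GC and length trend removed (0.671; range 0.000928 to 0.671). In R6/2 mice on PLX3397 against wild-type vehicle, choroid plexus genes had a median of -1.38 with 3 of 13 lower, 5 when adjusted over the list alone (camera adjusted p = 0.00289; 0.460 with an estimated correlation). Ribosomal protein genes rose with PLX3397 in wild type (median 0.43, camera adjusted p = 0.00104; 0.903 with an estimated correlation) and fell with it in R6/2 (median -0.30, camera adjusted p = 0.000485; 0.800 with an estimated correlation), with 0 of 30 called by limma in either. The call in wild type ended with the GC and length trend removed (0.0655) and without wild-type PLX3397 library 2 (0.0778), over a range of 1.20e-06 to 0.0778. The call in R6/2 ended without R6/2 vehicle library 1 (0.0760) and without both libraries high in choroid plexus genes (0.0590), over a range of 6.24e-08 to 0.0760.

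The interferon rise in R6/2 was weighed against 3 other sources. Its median was 1.19 with the GC and length trend removed and 0.94 without the libraries high in choroid plexus genes, which argues against either as the whole cause. If microglia carried the RNA, the 10 genes that rose would fall when microglia are removed, but PLX3397 moved them by a median of 0.10 in R6/2 (range -0.73 to 0.34), against a rise of 1.51 on vehicle, which argues against microglia as the main source for these 10 genes. A smaller share from microglia stays open. Irf7 was higher in R6/2 by 2.56 on vehicle and by 1.33 on PLX3397 (interaction -1.23, limma adjusted p = 0.0309). The antigen presentation list, tested apart, had means of 2.39 log2 CPM in wild-type vehicle, 3.20 in R6/2 vehicle and 2.55 in R6/2 PLX3397. A hypothesis is that the rise may come with the R6/2 genotype from cells other than microglia. Cell types were not separated here, so this stays open.

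Cortical and hippocampal genes were low in R6/2 PLX3397 libraries 1 and 2 (list means 2.21 and 2.10 log2 CPM) and in wild-type PLX3397 library 1 (2.40), against 3.60 to 5.36 in the others, so 3 of 6 PLX3397 libraries and 0 of 6 vehicle libraries were low. Of the 15 genes 60% were lower by 1 or more in both R6/2 PLX3397 libraries 1 and 2 than in library 3. Slc17a7 was at 2.79 and 3.06 log2 CPM in libraries 1 and 2 and at 8.995 in library 3. Prox1, among the others, was at 4.25 and 3.96 against 4.10. A cleaner dissection may be the cause, but it need not lower genes that striatal cells also make. Which of the 15 these are was not tested, so the share of 60% leaves dissection undecided. Library 3 differed from the R6/2 vehicle mean by -0.22, against -2.26 and -3.22 for libraries 1 and 2, and 1 library cannot decide whether the drug lowers these genes. Dissection and drug therefore cannot be told apart for these genes in R6/2.

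Splits of the 6 libraries of each pair of groups number 10, too few for a share under 0.05, and in each pair 1 split, the real one, gave as many calls as the real one. For R6/2 against wild type on vehicle the real count was 325 and the highest other 1, and for PLX3397 in wild type 2191 and 0 by limma (5246 at an unadjusted p under 0.05 in the real split). For PLX3397 in R6/2 these were 169 and 5, for the genotypes on PLX3397 5389 and 12, and for R6/2 on PLX3397 against wild-type vehicle 702 and 2.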
